A study of Homo sapiens with 12 samples.

How the data were processed

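Total RNA of MCF-7 cells transfected with siPRMT6 or siControl was hybridised to human exon arrays of Affymetrix, 1 array per sample and 6 per group, with biotin label, per the labels' protocols. Cells were grown with serum in DMEM/F-12 and RNA was purified with Trizol and then columns, per the labels' protocols. The deposited values, 1 per transcript cluster and array, were read as log2 values that had been normalized between arrays before they were deposited, as the values themselves show. With another log base their range would pass that of a scanner. The summary method, background correction and kind of normalization of the deposited values are not given in the sources used here. Their array medians lay between 4.53 and 4.58, and no array had a value below about 4.1, so the values had been scaled between arrays and have a floor, which compresses the changes of dim genes. No column belonged to another sample. Groups and replicate numbers came from the sample titles. Nothing states how the biological replicates were spaced, so p-values measure the spread between these samples.

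Clusters were named through the platform's annotation, matched by gene identifier to RefSeq of assembly GRCh38.p14. Clusters with several names or none were left out of the gene tests. Cluster numbers run along the chromosomes, and some clusters that carry a gene's name are numbered among genes of another place, as copies of a gene are. A cluster was therefore used only where at least 3 of the 10 single-cluster genes numbered next to it, 5 on each side, were neighbours of its gene in RefSeq (within 5 Mb). This rule was set after the data had been examined. It kept 20298 clusters of 17288 genes and left out 2668, besides 86 whose gene has no place in the reference. Of the 14721 genes with 1 cluster, 97.9% met it. All identifiers of the 17288 genes matched the reference. A gene's value was that of its brightest cluster over all 12 arrays, and 1865 genes had several. For a table of exon probe sets the design had set the median over a gene's probe sets instead. With the median over clusters 521 genes were called, of which 494 were among the 539 called with the brightest cluster. Genes were tested above the 90th percentile of the means of 275 olfactory receptor genes (4.83), which dropped 6296 genes, and PRMT6 was kept at any level. Without the rule on places 551 genes were called, of which 517 were among the 539 called with it.

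The test was limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table to read the values. It used lmFit and eBayes with 2 groups and no covariate, and Benjamini-Hochberg adjustment over all tested genes. A change is siPRMT6 minus siControl, and SE is the moderated standard error. PRMT6 was also given a two-sided exact permutation test over all regroupings of the arrays. The 34 lists were tested with camera at its preset correlation of 0.01, with at least 5 members tested, and again with a correlation estimated from each list. The design assumed that the table might hold exon probe sets. It holds 1 value per cluster, so the planned tests of exons against their gene were not analysed here. The comparison, the 34 lists and the rule for named genes were set before the data were examined. The rule takes PRMT6, the 12 largest rises and 12 largest falls among called genes with all 6 siPRMT6 arrays on 1 side of the siControl mean, 12 fixed genes, and up to 4 called members with the smallest p in each list past the camera threshold or with at least 3 called members. Genes outside this rule are named where a count is small (PSMB6, PSMB7, NDUFA9, CALR and SLC2A1) and under other observations. These were all chosen after their values were seen.

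On simulated data with the real genes' means and spreads and with noise independent between genes and arrays, 200 of 10992 genes were changed. The siPRMT6 against siControl test recovered 68.1% of those changed by 0.25, 90.6% by 0.5 and 100% by 1 on the log2 scale, with 12 false calls (6.52% of calls). The real arrays share variation between genes, with 39.7% of the residual variance in 1 component. The simulation leaves this out, so its rates need not hold for the real data. Alternatives fixed beforehand were other summaries of clusters, quantile normalization, equal array medians, the replicate number as a block, other filters on level, eBayes with trend and robust, array weights, a minimum of 1.5-fold, clusters of several genes, and each array left out. Alternatives added after seeing the data were clusters at any place, the median of clusters, no siControl replicates 5 and 6, a residual component as covariate or removed, cyclic loess, subtraction of the olfactory receptor median, and PRMT6 left out of its list. The group labels were also permuted in 100 splits. Signal over background limits what can be seen: genes near the floor can show smaller changes than occurred.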

Results

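Gene expression was measured in MCF-7 cells, an estrogen receptor positive line from a human breast cancer, after transfection with an siRNA against PRMT6 (siPRMT6, 6 arrays) or with a control siRNA (siControl, 6 arrays). PRMT6 is a protein arginine methyltransferase, an enzyme that methylates arginines of histone H3 and of other proteins. Each array held total RNA of a separate sample, which the labels call a biological replicate. The table of the series gives 1 log2 value per transcript cluster, the array's unit for a gene or a part of one. Of the clusters, 23052 carried the name of a single gene, 4597 carried several names and 269814 carried none. A gene was measured through the brightest of its own clusters, and 10992 genes were tested that lay above a background level of 4.83, set from olfactory receptor genes, or were PRMT6. The number of arrays in each group limits the precision.

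PRMT6 itself was lower on every siPRMT6 array than on every siControl array. Its level was 5.18 ± 0.08 (SD, n = 6) with siPRMT6 and 5.69 ± 0.19 (SD, n = 6) with siControl, so PRMT6 fell by 0.52 ± 0.08 (SE) on the log2 scale. This left 69.9% of the control value, with a 95% confidence interval from 62.4% to 78.4%. PRMT6 was read by 1 transcript cluster, 2349848. The highest siPRMT6 array stood at 5.27 and the lowest siControl array at 5.43. In the two-sided exact permutation test, 2 of 924 regroupings of the arrays gave a difference as large, p = 0.00216, the smallest value this design allows. The limma test gave a Benjamini-Hochberg adjusted p of 0.00321. With the olfactory receptor median subtracted on the linear scale, an alternative chosen after the data were seen, the change of PRMT6 was -0.999 ± 0.14 (SE), or 50.03% of control (95% interval 40.6% to 61.6%).

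**Figure D1:**
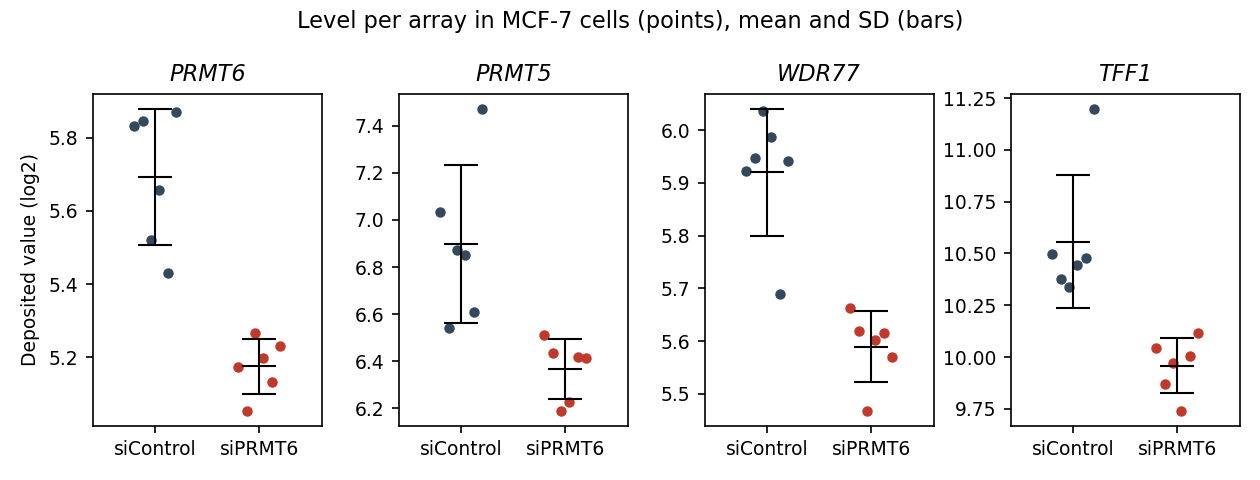
Deposited log2 values of PRMT6, PRMT5, WDR77 and TFF1 on each array (points), with the mean and SD of each group of 6 arrays (bars); the axes are in log2 units and do not start at 0. All siPRMT6 arrays of PRMT6 lie at or below 5.27 and all siControl arrays at or above 5.43, and the highest value of TFF1, 11.2, belongs to siControl replicate 6.

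The design asks which genes differ between cells given siPRMT6 and cells given siControl. Far more genes fell than rose: 416 of the 10992 tested genes fell and 123 rose. Most changes were small, with a median size of 0.29 on the log2 scale among these 539 genes, and 29 genes (11 up, 18 down) changed at least 1.5-fold. The falls included PARK7, a protein that protects cells from oxidative stress, at 0.591 times its control level, and APLP2, a relative of the amyloid precursor protein, at 0.643 times. The rises included ADAMTS19, a secreted metalloprotease, higher by 72.7%, and ABCA12, a lipid transporter, higher by 59.6%. Calls were made with limma at a Benjamini-Hochberg adjusted p under 0.05, and 2007 genes had an unadjusted p under 0.05. In 406 genes the groups did not overlap, where regrouping at random gives 0.216% of genes. The count moved with single arrays: it was 1293 without siControl replicate 5, 345, 309, 288 and 321 without siPRMT6 replicates 2, 3, 4 and 5, and 332, 317 and 320 without siControl replicates 1, 3 and 4. It was 1919 with array weights and, in fits chosen after the data were seen, 1808 without siControl replicates 5 and 6, 1544 with the residual component as covariate and 1641 with it removed. That component was the largest one left in the same values after the group means were removed. Both fits that use it therefore lower the residual spread by construction, which favours more calls.

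Among the 12 genes with the largest falls, CERS2, a ceramide synthase, fell by 0.88 ± 0.10 (SE) and FKBP4, a co-chaperone of steroid hormone receptors, fell by 0.78 ± 0.08 (SE; adjusted p = 0.00101 and 3.01e-04). PARK7 fell by 0.76 ± 0.05 (SE), from 6.22 ± 0.09 to 5.46 ± 0.07 (SD, n = 6 each; adjusted p = 6.90e-06), and APLP2 fell by 0.64 ± 0.04 (SE; adjusted p = 8.53e-06). NCOA4, which carries ferritin to the lysosome, fell by 0.73 ± 0.08 (SE), and CS, the citrate synthase of the mitochondrial matrix, fell by 0.65 ± 0.10 (SE). ISG20L2, a nucleolar exonuclease, fell by 0.94 ± 0.14 (SE), PIP4K2C, a phosphoinositide kinase, by 0.84 ± 0.14 (SE) and LYSET, a protein needed to sort lysosomal enzymes, by 0.66 ± 0.13 (SE). GPR27, an orphan receptor, had the largest fall, -1.02 ± 0.24 (SE; adjusted p = 0.0312), and SERPINA3, a secreted protease inhibitor, fell by 0.94 ± 0.22 (SE; adjusted p = 0.0314). NPIPB3, a member of a family of near-identical genes and therefore uncertain, fell by 1.001 ± 0.15 (SE). The groups did not overlap for 11 of these 12 genes, GPR27 being the exception, and 39 called genes fell by more than PRMT6. The call of GPR27 was kept in 4 of the 12 fits that each left out 1 array, and so was that of SERPINA3. With clusters of several genes added, a brighter cluster gave GPR27 a value of 0.042 (adjusted p = 0.815; from 0.00274 over all settings), and with clusters numbered elsewhere in the genome, chosen after the data were seen, NPIPB3 was at 0.15 (adjusted p = 0.890; from 8.38e-05 over all settings).

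Among the 12 genes with the largest rises, 4 had a single cluster: ADAMTS19, ABCA12, COX6C, a subunit of cytochrome c oxidase, and the pseudogene FAM136CP. ADAMTS19 rose by 0.79 ± 0.11 (SE; adjusted p = 0.00279), ABCA12 by 0.67 ± 0.12 (SE; adjusted p = 0.00998), COX6C by 0.63 ± 0.12 (SE; adjusted p = 0.0121) and FAM136CP by 0.58 ± 0.14 (SE; adjusted p = 0.0337). PDK3, a kinase that inhibits pyruvate dehydrogenase, rose by 0.63 ± 0.13 (SE), and its other 4 clusters, all above background, lay between 0.08 and 0.69. TRIQK rose by 0.61 ± 0.12 (SE), against 0.73 ± 0.17 and 0.10 ± 0.05 (SE) in its other 2 clusters. GPRIN3 rose by 0.75 ± 0.15 (SE), against 0.35 ± 0.14 and 0.11 ± 0.03 (SE) in its other 2 clusters. MYO6, the motor protein myosin VI, rose by 0.81 ± 0.15 (SE) in the cluster used and was at -0.06 ± 0.11 (SE) in its other cluster. QSOX1, a disulfide-forming enzyme, rose by 0.79 ± 0.18 (SE), against 0.03 ± 0.04 and 0.02 ± 0.09 (SE) in its other 2 clusters. SLC44A1, a choline transporter, rose by 0.72 ± 0.18 (SE), against 0.11 ± 0.05 and 0.20 ± 0.12 (SE) in its other 2 clusters above background. TMEM132C showed the largest rise, 0.87 ± 0.17 (SE), and TMEM135 rose by 0.70 ± 0.14 (SE), with all their other clusters below background. The medians over the clusters of MYO6, QSOX1, SLC44A1, PDK3 and GPRIN3 were 0.37, 0.05, 0.18, 0.52 and 0.35 and did not pass the threshold (adjusted p = 0.102, 0.796, 0.223, 0.289 and 0.154, the highest over all settings; the lowest were 3.71e-05, 1.65e-04, 4.95e-04, 0.00146 and 9.50e-04), nor did the mean over those of TMEM135 (0.16, adjusted p = 0.204; from 0.00125 over all settings). The calls of SLC44A1 and FAM136CP were each kept in 4 of the 12 fits that left out 1 array. FAM136CP was at 4.80 with siControl, below the background level of 4.83, and at 5.38 with siPRMT6.

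**Figure D2:**
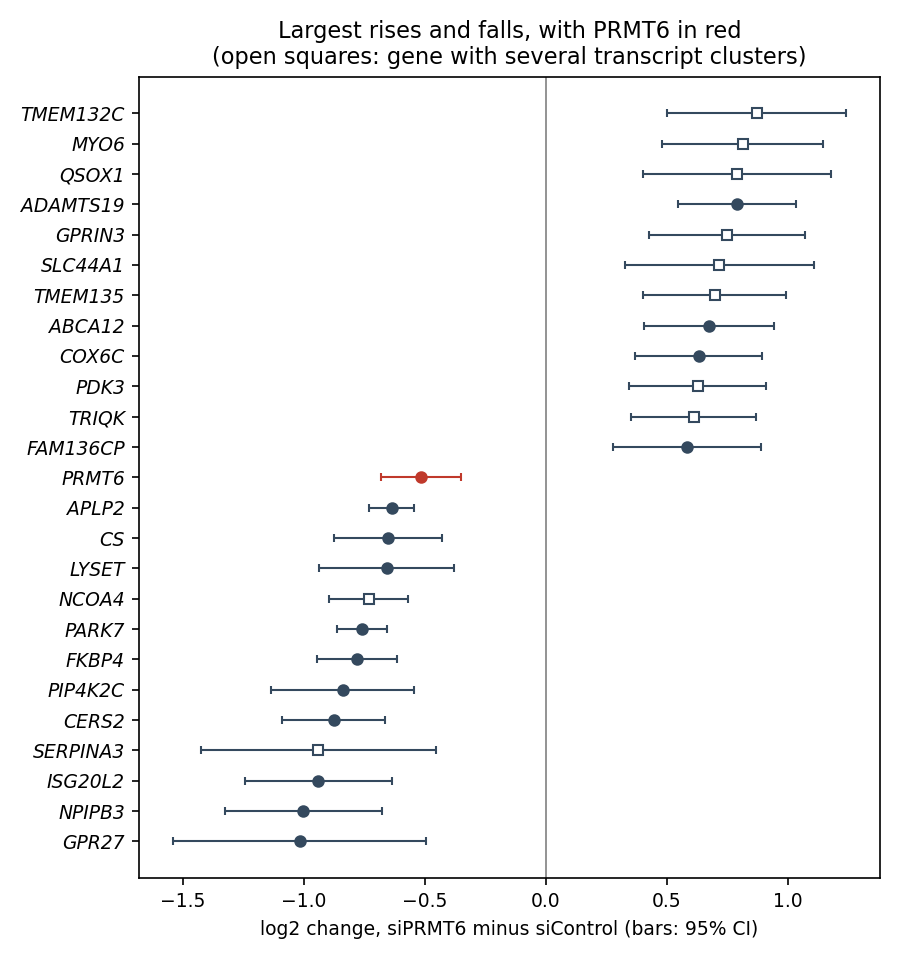
Log2 change, siPRMT6 minus siControl (horizontal axis), of PRMT6 and of the 12 genes with the largest falls and the 12 with the largest rises, each with its 95% confidence interval from limma over 6 arrays per group. The changes run from -1.02 (GPR27) to 0.87 (TMEM132C), with PRMT6 at -0.52, and open squares mark genes with several transcript clusters.

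The next question was whether genes of a pathway, complex or cell type moved together, tested on 34 lists. Of 27 subunits tested of the proteasome, the complex that degrades ubiquitin-tagged proteins, 6 fell, none rose and 21 did not pass, and 13 fell when adjusted over the list alone. The median change of the subunits was -0.18, camera gave an adjusted p of 3.57e-08, and the adjusted p was 0.589 with an estimated correlation. PSMB4 fell by 0.63 ± 0.12 (SE; adjusted p = 0.00951), PSMD11 by 0.42 ± 0.08 (SE), PSMB3 by 0.36 ± 0.07 (SE) and PSMB2 by 0.21 ± 0.04 (SE), beside PSMB6 and PSMB7. With the mean of its 2 clusters PSMB2 was at -0.11 and did not pass (adjusted p = 0.118; from 0.00110 over all settings). With the replicate number as a block PSMD11 and PSMB2 did not pass (adjusted p = 0.0542 and 0.0667). Of 9 protein arginine methyltransferases and partners tested, 4 fell, none rose and 5 did not pass (5 fell when adjusted over the list alone). The 4 were PRMT6, PRMT5, which makes symmetric dimethylarginine, its partner WDR77, and PRMT3, which acts on a ribosomal protein. PRMT5 fell by 0.53 ± 0.13 (SE; adjusted p = 0.0355), PRMT3 by 0.41 ± 0.09 (SE; adjusted p = 0.0214) and WDR77 by 0.33 ± 0.06 (SE; adjusted p = 0.00596). The list, which holds the target of the siRNA, had a camera adjusted p of 0.00204, and an adjusted p of 0.589 with an estimated correlation. With PRMT6 left out, an alternative chosen after the data were seen, the mean of the list was -0.20 and the camera adjusted p 0.0157. PRMT5 kept its call in 4 and PRMT3 in 8 of the 12 fits that each left out 1 array.

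Of 34 subunits of oxidative phosphorylation tested, 4 fell, 1 rose and 29 did not pass, and 9 fell and 1 rose when adjusted over the list alone. UQCRB, of complex III, fell by 0.61 ± 0.12 (SE; adjusted p = 0.0143), ATP5MC1, of the ATP synthase, fell by 0.36 ± 0.09 (SE; adjusted p = 0.0387), COX5A fell by 0.16 ± 0.04 (SE; adjusted p = 0.0382), NDUFA9 fell as well, and COX6C rose. The median was -0.11, camera gave an adjusted p of 0.00204, and the adjusted p was 0.793 with an estimated correlation. ATP5MC1 kept its call in 3 and COX5A in 2 of the 12 fits that each left out 1 array, and UQCRB was at -0.16 (adjusted p = 0.455; from 8.52e-05 over all settings) with clusters of several genes added. None of 13 canonical histone genes passed the threshold, with a median of -0.22 and 1 that fell when adjusted over the list alone. Their list had a camera adjusted p of 0.0104, and an adjusted p of 0.793 with an estimated correlation. Of 10 nonsense-mediated decay targets and factors, SMG8, a cofactor of the kinase that starts this decay, fell by 0.39 ± 0.08 (SE; adjusted p = 0.0198), 9 did not pass, and 5 fell when adjusted over the list alone. SMG8 kept its call in 11 of the 12 fits that each left out 1 array, and lost it with the replicate number as a block (adjusted p = 0.0688). The camera adjusted p of this list was 0.0157, and its adjusted p was 0.589 with an estimated correlation. The camera adjusted p was 0.115 without siControl replicates 5 and 6, 0.223 with clusters at any place and 0.0690 with array weights, the first 2 chosen after the data were seen, and the range over all settings began at 0.00419.

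Few hypoxia targets or basal and mesenchymal markers passed the threshold, and those that did rose. Of 16 hypoxia targets, LOX, an enzyme that crosslinks collagen, rose by 0.51 ± 0.10 (SE; adjusted p = 0.0143), 15 did not pass, and 3 rose when adjusted over the list alone. The median was 0.09, camera gave an adjusted p of 7.07e-04, and the adjusted p was 0.437 with an estimated correlation. Among the hypoxia targets VEGFA was at 0.0071 (adjusted p = 0.945) and SLC2A1 at -0.03 (adjusted p = 0.773). Of 9 basal and mesenchymal markers, 2 rose and 7 did not pass, with the same 2 counted when adjusted over the list alone. CD44, a cell surface receptor for hyaluronan, rose by 0.26 ± 0.04 (SE; adjusted p = 0.00433) and CAV1, a coat protein of caveolae, rose by 0.20 ± 0.04 (SE; adjusted p = 0.0142). Both were dim: CD44 was at 4.81 with siControl and 5.07 with siPRMT6, and CAV1 at 4.80 and 5.01. Their siControl means lay below the background level of 4.83. The camera adjusted p was 0.0157, and the adjusted p was 0.404 with an estimated correlation. With the median over clusters above background the mean of this list was -0.02 and with genes above the median level it was -0.01 (camera adjusted p = 0.548 and 0.657; from 0.00796 over all settings). None of the 7 lists passed with an estimated correlation. The proteasome, oxidative phosphorylation and histone lists were bright, at means of 6.25, 6.06 and 6.16 with siControl. In the brightest of 5 equal parts of the tested genes, from 5.85 up, the median change was -0.062. The medians of the 3 lists, -0.18, -0.11 and -0.22, lay further below 0. Whether this shift of bright genes accounts for part of their falls was not tested.

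**Figure D3:**
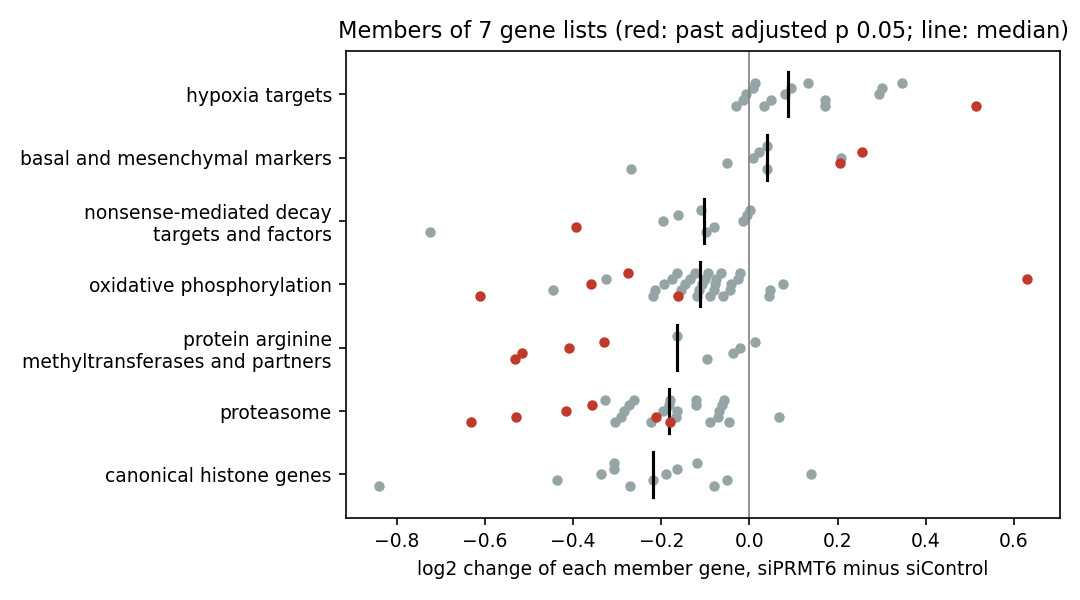
Log2 change, siPRMT6 minus siControl, of each member gene (points) of the 7 lists past a camera adjusted p of 0.05, with members past the threshold over all genes in red and the list median as a line. Of the 27 proteasome subunits 26 lie below 0, and of the 16 hypoxia targets 13 lie above 0.

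The other 26 lists tested had camera adjusted p from 0.0808 to 0.955. In 3 of them, at least 3 members passed the threshold over all genes. Of 25 targets of p53, the tumor suppressor, 3 fell, none rose and 22 did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 0.0808; adjusted p = 0.843 with an estimated correlation). TNFRSF10B, a death receptor, fell by 0.36 ± 0.06 (SE; adjusted p = 0.00825) and TP53I3, an oxidoreductase, by 0.22 ± 0.05 (SE; adjusted p = 0.0381). PLK3, a kinase, fell by 0.41 ± 0.10 (SE; adjusted p = 0.0408) in the cluster used and was at -0.03 ± 0.04 (SE) in its other cluster above background. With clusters of several genes added PLK3 was at 0.13 (adjusted p = 0.450; from 0.0132 over all settings). PLK3 and TP53I3 each kept the call in 4 of the 12 fits that left out 1 array. Of 31 estrogen-induced genes 3 fell, none rose and 28 did not pass, while 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.883). The median and mean of this list were -0.02 and -0.03, while the direction of its camera test was up. TFF1, a secreted trefoil peptide, fell by 0.60 ± 0.13 (SE), from 10.56 ± 0.32 to 9.96 ± 0.13 (SD, n = 6 each; adjusted p = 0.0186), and siControl replicate 6 held its highest value, 11.2. IGFBP4, which binds insulin-like growth factors, fell by 0.35 ± 0.04 (SE; adjusted p = 0.00159) and SIAH2, a ubiquitin ligase, by 0.16 ± 0.04 (SE; adjusted p = 0.0447), a call kept in 1 of the 12 fits that left out 1 array. Of 28 genes of the unfolded protein response and of ATF4, 3 fell, 2 rose and 23 did not pass, and 5 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.955). The folding enzyme PDIA4 rose by 0.32 ± 0.06 (SE; adjusted p = 0.0115) and the lipoprotein receptor VLDLR by 0.19 ± 0.04 (SE; adjusted p = 0.0309), while the mitochondrial folate enzyme MTHFD2 fell by 0.34 ± 0.08 (SE; adjusted p = 0.0270), the co-chaperone DNAJB9 by 0.17 ± 0.04 (SE; adjusted p = 0.0217) and CALR fell too. VLDLR kept the call in 6, MTHFD2 in 8 and DNAJB9 in 10 of the 12 fits that each left out 1 array, and MTHFD2 was at -0.13 (adjusted p = 0.697) as a median over its clusters. As checks for other cell types, none of 6 leukocyte markers (camera adjusted p = 0.552) and none of 3 fibroblast markers tested passed, the latter too few for camera.

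Of 10 tested genes tied to PRMT6 or to estrogen signalling, TFF1 alone passed the threshold. The cell cycle inhibitor CDKN1A was at -0.03 ± 0.05 (SE; adjusted p = 0.777) and CDKN1B at -0.12 ± 0.04 (SE; adjusted p = 0.127). The angiogenesis inhibitor THBS1 was at 0.19 ± 0.07 (SE; adjusted p = 0.128), a value that passed with array weights (0.19, adjusted p = 0.0228), without siControl replicate 6 (0.24, adjusted p = 0.0389) and without siControl replicates 5 and 6 (0.21, adjusted p = 0.0325), in a range up to 0.225 over all settings. The estrogen receptor gene ESR1 was at -0.09 ± 0.06 (SE), PGR at 0.02 ± 0.06, GREB1 at -0.10 ± 0.08 and CCND1 at -0.10 ± 0.08 (adjusted p = 0.505, 0.890, 0.608 and 0.576). VEGFA was at 0.0071 ± 0.04 (SE; adjusted p = 0.945) and SYK, a tyrosine kinase, at 0.09 ± 0.11 (SE; adjusted p = 0.730). CDKN1B passed with array weights (-0.12, adjusted p = 0.0289), without siControl replicates 5 and 6 (-0.15, adjusted p = 0.0488), and with the residual component as covariate (-0.12, adjusted p = 0.0142) or removed (-0.11, adjusted p = 0.0165), in a range up to 0.249. ESR1 passed in the first 2 of these fits (-0.15, adjusted p = 0.0220, and -0.18, adjusted p = 0.0102), in a range up to 0.743. Both fits with the residual component lower the residual spread by construction, so the passes of CDKN1B in them carry little weight. CDKN1B, PGR, ESR1 and CDKN1A were dim, at 5.00, 5.01, 5.35 and 5.38 with siControl, against a background level of 4.83. The floor compresses the changes of dim genes, so these values do not show that the genes were unchanged. TP53 carried no named cluster and MYC lay below the background level, so neither was tested. The title of the series also names splicing, which was not analysed here, since each value covers a whole transcript cluster.

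The arrays themselves differed within groups. The first principal component held 33.8% of the variance, with siControl replicate 5 at 13.4 beside siPRMT6 replicates 3 and 6 at 11.7 and 13.5. The second held 24.0%, with siControl replicate 6 at -21.2. Those 2 siControl arrays correlated with the rest of their group at a mean of 0.925 and 0.930, and the other siControl arrays at 0.954 to 0.958. The mean over all tested genes was 5.60 on siControl replicate 6 and between 5.49 and 5.54 on the other siControl arrays.

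**Figure D4:**
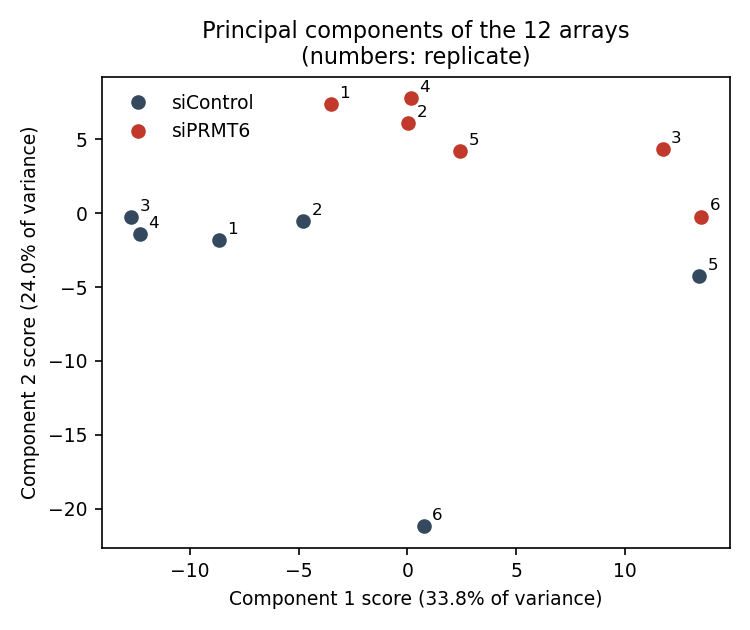
Scores of the 12 arrays on the first 2 principal components of the tested genes (both axes in units of the component score), with the replicate number beside each point. On component 1, siControl replicate 5 lies at 13.4 near siPRMT6 replicates 3 and 6, and siControl replicate 6 lies at -21.2 on component 2.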

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

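The tests of a mislabelled or mixed siControl replicate 5 and of an axis within both groups were chosen after the results were seen, as were cyclic loess, the removal of the axis from the values and the subtraction of the olfactory receptor median. In 13 of 132 groups of 6 arrays the highest or lowest array lay far from the rest, where chance gives about 6.6. Of these arrays, 5 were siControl replicate 5 and 5 were siControl replicate 6. siControl replicate 6 was the highest of its group for TFF1 (11.2, next 10.50), SERPINA3 (8.82, next 7.58) and ATP5MC1 (6.58, next 6.12) and the lowest for PDK3 (8.91, next 9.49) and TMEM132C (5.60, next 6.06). siControl replicate 5 was the lowest for PARK7 (6.04, next 6.22), WDR77 (5.69, next 5.92), TNFRSF10B (5.66, next 5.89), SIAH2 (5.40, next 5.57) and ADAMTS19 (5.64, next 6.20). siPRMT6 replicate 3 was the lowest for FKBP4 (8.43, next 8.63), siControl replicate 3 the highest for SLC44A1 (6.03, next 5.26) and siControl replicate 4 the highest for TMEM135 (5.86, next 5.19). Without the array in question all of these genes kept their direction and passed the threshold, for example TFF1 at -0.47 (adjusted p = 0.00241) and SERPINA3 at -0.70 (adjusted p = 0.00152). Leaving out the most extreme array of a group lowers its spread by construction, so this does not show that a call is stable. Over the 12 fits that each left out 1 array, SIAH2 kept its call in 1, ATP5MC1 in 3, and SERPINA3 and SLC44A1 in 4. The other genes of this paragraph kept theirs in all 12.

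Signal also lay outside the named genes. Of 88369 clusters above background without a gene name, 498 passed the threshold (235 rose, 263 fell; 11464 had an unadjusted p under 0.05). Falls and rises were closer in number there than among the tested genes, where 416 fell and 123 rose. Clusters 3154315 and 3957849 rose by 2.10 ± 0.24 and 1.79 ± 0.19 (SE), cluster 2426263 fell by 2.18 ± 0.25 (SE) and cluster 3995837 fell by 2.01 ± 0.27 (SE). Of 3041 clusters with several gene names, 60 passed.

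siControl replicate 5 stood apart from its group: without it 1293 genes passed in place of 539. Over the genes called without it, a score of 0 marks the mean of the other siControl arrays and 1 that of the siPRMT6 arrays. siControl replicate 5 scored 0.86 on the 1102 genes that fell but -0.045 on the 191 that rose, within the range of the other siControl arrays (-0.13 to 0.12). Its PRMT6 level, 5.43, was the lowest of the siControl arrays (the others 5.52 to 5.87) and above the highest siPRMT6 array (5.27), which goes with a mixed sample, while the score on the genes that rose argues against a mislabelled or mixed sample as the whole account. An axis of variation within both groups, not tied to the siRNA, may account for it: siPRMT6 replicate 6 lay beyond 1 SD on the same side (1.22 SD, against 1.85 for siControl replicate 5), which is 1 of the 6 siPRMT6 arrays. The group means were removed before this axis was computed, so some siPRMT6 arrays lie on that side by construction. The test therefore cannot decide between such an axis and a mixed sample. Of 100 splits of the 12 arrays 2 called at least 539 genes, the real one included, a share under the 0.05 set as bound. These splits are a sample of all regroupings into 6 and 6, so the share is itself uncertain and does not exclude chance. The highest other split called 1045, more than the real one. It exchanged siControl replicate 5 with siPRMT6 replicate 1, which points to a structure among the arrays. For the lists the share was above the bound: 28 of 100 splits put at least 7 lists past the camera threshold, and the highest other split put 14, so chance is not excluded there either.

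More genes fell than rose: 77.2% of the called genes fell (exact binomial 95% interval 73.4% to 80.7%). This interval and those below treat genes as independent, which genes on the same arrays are not, so they are too narrow. Without single arrays the share ranged from 68.6% (without siPRMT6 replicate 3) to 85.2% (without siControl replicate 5). After cyclic loess the share was 79.6% (75.8% to 83.0%), above the 60% set as its bound. Cyclic loess was fitted over all clusters, most of them without a gene name. The median change of the tested genes was -0.0158 after it and -0.0112 before. It is not shown that it removed level-dependent differences among the tested genes, so the test does not decide on them. Without siControl replicate 6 the share was 75.3% (71.2% to 79.0%), so that array is not the whole cause. With the axis of variation within groups removed from the values, its group difference included, it was 69.1% (66.8% to 71.3%), above the 60% set as its bound. An effect of PRMT6 loss and an off-target effect of its siRNA stay open and were not tested, since the sequence of the siRNA is not given in the sources used here and the design holds 1 treated group.

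In 39 called genes the fall was larger than that of PRMT6, the target of the siRNA. A candidate explanation is the floor of the values, which compresses a dim gene such as PRMT6. After subtraction of the olfactory receptor median 18 called genes fell by more than PRMT6, 17 of them also called on the deposited scale. Only 4 of the 18 lay beyond the lower 95% bound of PRMT6. The count is thus above the limit of 5 set for this test, which was itself chosen after the results were seen. It is not beyond the spread of PRMT6's own fall, and the floor stays open. No biological explanation was tested.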

How the results depend on the processing

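The fits without siControl replicates 5 and 6, with the residual component, with clusters at any place, with the median of clusters, with cyclic loess, with background subtraction and with PRMT6 left out of its list were chosen after the data were seen. The fall of PRMT6 kept its direction and its side of the threshold under all 13 alternatives (-0.999 to -0.52) and without each array (-0.57 to -0.48). The number of genes changed stayed within 1.5 times under 12 of 18 alternatives (436 to 623). The rule that a cluster lie at its gene's own place was also set after the data were seen. Genes changed, rose and fell numbered 1919, 469 and 1450 with array weights, 1808, 434 and 1374 without siControl replicates 5 and 6, 1544, 444 and 1100 with the residual component as covariate, 1641, 507 and 1134 with it removed, and 29, 11 and 18 at a minimum of 1.5-fold, where the added limit itself removes genes. Without each array in turn they ranged from 288 to 1293, 65 to 191 and 212 to 1102. The residual component was taken from the same values, so both fits that use it lower the residual spread by construction and favour more calls. Lists past the threshold numbered 7, 11 without a filter on level, 11 without siControl replicates 5 and 6 and 0 with an estimated correlation, and 7 to 10 without each array. Except where the construction shows it, the cause was not tested.

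The replicate numbers showed no clear pairing of the arrays, and the labels do not say whether same-numbered arrays were handled together. Same-numbered arrays deviated together with correlations of 0.42, 0.31 and 0.41 for replicates 1, 4 and 6. The other numbers gave 0.09, -0.42 and -0.17, and 1 of 6 siPRMT6 arrays matched its own number best. The check cannot exclude a pairing. With the replicate block 333 genes were called, 80 rose and 253 fell. GPR27, PRMT5, PSMD11, PSMB2, PLK3, SMG8, ATP5MC1, SIAH2, COX5A, VLDLR, FAM136CP, TMEM135 and SLC44A1 lost their call with it (adjusted p from 0.0542 to 0.0990).

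Of the 48 named genes past the threshold besides PRMT6, 26 stayed past it under every alternative that tested them and 24 of these also without each array. Of these 26, CD44 and CAV1 were tested under 12 and 14 alternatives, since some fits left them out, and the others under 17. Over all named genes and settings 1443 values were alike, 171 lost the threshold, 9 gained it and 12 changed sign. The sign changed for GPR27 (0.042) and PLK3 (0.13) with clusters of several genes added, NPIPB3 (0.15) with clusters at any place, SYK (-0.031) with the mean of clusters, VEGFA (-0.0021) with the residual component removed, and PGR with array weights (-0.013) and without siControl replicates 5 and 6 (-0.052), and the cause was not tested. Without single arrays VEGFA ranged from -0.014 to 0.021 and PGR from -0.011 to 0.052. The alternatives meant for exon probe sets were not run, since the values are of whole clusters. Genes near the background level of 4.83 limit what can be seen.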

Other observations

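The genes named here and the test of neighbouring genes were chosen after the results were seen. Other members of the lists passed the threshold over all genes. KRT19, a keratin of luminal cells, fell by 0.53 ± 0.08 (SE; adjusted p = 0.00422), the only called member of 15 luminal markers (camera adjusted p = 0.228; adjusted p = 0.890 with an estimated correlation). DPY30, a subunit of the complexes that methylate lysine 4 of histone H3, fell by 0.41 ± 0.07 (SE; adjusted p = 0.00959), the only one of 13 (camera adjusted p = 0.234). Of 35 genes of G1/S and DNA replication, the thymidylate synthase TYMS rose by 0.33 ± 0.04 (SE; adjusted p = 0.00188) and the replication licensing factor CDC6 fell by 0.42 ± 0.09 (SE; adjusted p = 0.0180). PRC1, a protein of the spindle midzone, fell by 0.48 ± 0.08 (SE; adjusted p = 0.00616), the only one of 34 genes of G2/M and mitosis. COL12A1, a collagen, rose by 0.32 ± 0.04 (SE; adjusted p = 0.00123), the only one of 16 genes of extracellular matrix and angiogenesis. Of 33 cytosolic ribosomal proteins RPL5 rose by 0.42 ± 0.11 (SE; adjusted p = 0.0496) and RPLP1 fell by 0.42 ± 0.08 (SE; adjusted p = 0.0143). None of 27 core spliceosome genes passed, and of 15 SR and SR-like splicing factors SRRM2 fell (adjusted p = 0.0347).

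Falls were more frequent among bright genes: of 5 equal parts of the tested genes by level, the brightest held 176 that fell and 48 that rose, and the dimmest 26 and 20. The median change of all genes in a part, called or not, was -0.062 in the brightest and 0.003 in the dimmest. A hypothesis was that a stretch of neighbouring genes rose together. The highest mean change over 20 neighbouring genes in RefSeq's order was 0.10, from TSPAN4 to IGF2, with none of the 20 called. In a permutation of the gene order a share of 0.159 of 1000 shuffles reached it, above the 0.05 set as bound, while the median of the shuffled maxima was lower, at 0.08. The test leaves such a stretch open.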
